A study of Mus musculus with 15 samples.

How the data were processed

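Gene expression was measured on Illumina mouse bead arrays in primary cortical neurons of Swiss albino mice, prepared at gestational day 15 to 16 and grown for 5 days, per the labels. Kainate, an agonist of the AMPA and kainate types of glutamate receptor, was applied at 100 µM for 5 h, 15 h or 24 h, with 3 arrays per time. The 6 control arrays carried vehicle-treated neurons with a treatment time of 0. Total RNA was purified on RNeasy columns and labelled as biotinylated cRNA with a MessageAmp kit, per the labels' protocols. The 15 arrays lay on 3 beadchips, each with 2 controls and 1 array of every kainate time. Each group sat at fixed positions of the chip and every control has time 0, so neither the position nor the hours in culture can be separated from the treatment. The labels do not state that the replicates are separate cultures, so the p-values measure only the spread between these samples.

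The signal of a target is a mean bead intensity, which the authors exported from BeadStudio 3.2.3 with normalization and error model set to none, per the file headers. The deposited detection scores are a fraction, 1 minus the detection p-value against the negative control beads of the array, a direction checked on the values. The number of beads behind each mean was deposited beside them. The authors' normalized table holds a ratio on the linear scale. Its values equal each array's signals divided by the array median and then each target divided by the median of the 6 controls, a rule derived from the values because no header states it. The series matrix holds the same deposited ratio for 24454 probes. Of 24611 targets in the gene profile, 4 were bacterial controls and the other 24607 carried values in the non-normalized table. A further 9 arrays of the gene profile matched no sample, and their 72 columns were not used in any step.

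Genes were named from the platform annotation, with symbols updated through the Entrez number to the reference gene table of assembly GRCm38.p6. That gave 1 symbol to 20854 targets and none to 3752, while 1 target had several and stayed unnamed. There were 15923 different symbols. The accession column deposited beside the signals named the same gene as the platform annotation for 0.14% of 17376 targets with both. It was therefore not used, and why it differs was not tested. The Entrez number inside the target identifier and the platform annotation named the same gene for 98.2% of 7716 targets with both.

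Background correction, an offset of 16, quantile normalization and log2 transformation followed limma's neqc, with the negative controls inferred from the detection p-values. In a first run this step failed on 5 arrays (control replicates 1 and 3 and the 3 arrays at 5 h), where the inferred spread of the negative controls was 107.5 to 179.8 intensity units against 5.4 to 7.1 on the other arrays. The source was 1 target with signals of 4487 or more on all arrays but a detection p above 0 on those 5. On every other target the brightest signal with a detection p above 0 was 77. Any target with a signal over 1000 and a detection p above 0 was then left out, which removed that 1 target, kept 24606 and brought the spread to 5.4 to 7.6. This repair was made after the data were seen, and every result had first been computed with the scores as deposited.

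Probes with a detection p below 0.05 on at least 3 of the 15 arrays were tested, 14154 in all, of which 1844 carry no gene symbol. Limma's lmFit and eBayes fitted 4 group means to all 15 arrays, and moderated two-sided tests were made for each kainate time against the controls and between the kainate times, 6 contrasts in all. Benjamini-Hochberg adjusted p below 0.05 was the threshold, and a gene rose, fell or changed only where its probe passed it. A moderated F test asked for a change at any time. Errors of fold changes are standard errors from the model, with 6 controls and 3 arrays per kainate group, and the residual degrees of freedom with the prior were 15.8. Where a probe was not detected on any array of its dimmer group, the fold is a bound, "at least N-fold": the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own signal and the lowest signal among detected probes. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

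Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe per gene (the brightest), among 9824 genes, and adjusted over the 33 lists of a contrast. Camera asks whether a list moved relative to the other genes. The 8 lists of cell type markers were astrocyte, oligodendrocyte lineage, microglia and macrophage, endothelial and mural, fibroblast and meningeal, neural progenitor, erythroid, and excitatory cortical neuron. The 25 pathway lists covered immediate early genes, ionotropic glutamate receptors, presynaptic, postsynaptic and GABAergic genes, neuronal cytoskeleton, voltage-gated channels, calcium handling, calpains and cathepsins, cell cycle, p53 targets, apoptosis, the unfolded protein response, ATF4 targets, NRF2 targets, heat shock, oxidative phosphorylation, glycolysis, cholesterol biosynthesis, proteasome, lysosome, inflammation, interferon, ribosomal proteins and growth factors. List members were counted as rising or falling by the test over all probes and again with p-values adjusted over the list alone.

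The genes named are, for each kainate time, the 6 largest rises and 6 largest falls among probes past the threshold with a gene symbol that is not a clone or accession name, detected on all arrays of the higher group and with every kainate array beyond every control, a second probe of a gene being passed over. The 3 largest rises and falls from 5 h to 15 h and from 15 h to 24 h follow the same rule. Up to 4 members of each list with the smallest F-test p and all measured ionotropic glutamate receptor subunits were added.

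The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were no background correction, normexp with an offset of 50, median centring, the authors' ratios and the series matrix on the log2 scale, no filter, a filter at a detection p below 0.01 on all arrays of a group, trended and robust eBayes, array weights, blocks for the beadchip or the labelled replicate numbers, a random block for the beadchip, fits of only the 2 groups compared, limma's treat against a fold of 1.2, an estimated correlation, the mean of all probes of a gene, fry, controls split into separate sets of 3, and leaving out each array in turn. With trended and robust eBayes or the random block, lists were tested with limma's cameraPR on the t-statistics instead of camera. Further alternatives were chosen after the data were seen. They were the detection scores as deposited, a robust background, centring on the probes detected on all arrays, control replicates 1 and 3 left out, these and 24 h replicate 3 left out, and the 5 arrays named above against the other 10 as a block.

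Overlaps between times were set beside 100 simulations of unchanged groups against the same controls, beside independent lists of the same sizes, and beside fits with the controls split into separate sets of 3. The fit was tested on simulated data with 200 changed probes among 14154 at 5 h. It recovered 6% of 50 probes changed by 1.25-fold, 58% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 4 false calls. At 15 h and 24 h, simulated without any change, it made 0 false calls. The simulated noise was independent between probes, and far fewer probes changed than were called on these arrays. These rates therefore check the fit and do not give the error rate of the real calls. The number of arrays limits the precision of every value.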

Results

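The series follows gene expression during kainate-induced death of cultured cortical neurons. The 15 arrays comprise 6 vehicle controls and 3 arrays each after 5 h, 15 h and 24 h with 100 µM kainate. Median signals were 53.4 to 70.4 intensity units per array, each target was the mean of a median of 34 or 35 beads, and 49.5% to 55.2% of the targets were detected. Correlations across probes between arrays of a group were 0.978 to 0.996 for the controls, 0.994 to 0.996 at 5 h, 0.995 to 0.996 at 15 h and 0.986 to 0.994 at 24 h. The first principal component held 51.6% of the variance and the second 19.5%. Control replicates 1 and 3 stood apart from the other 4 controls. When each of the 15 pairs of controls was set against the other 4, that pair gave 1900 called probes and each of the other 14 pairs gave 0.

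The comparison of 5 h with the controls asks for the early response to kainate, and its largest changes were in activity-regulated transcription factors. Fosb (ILMN_2778279), a partner of Jun in the AP-1 factor, rose by 7.33 ± 0.19 on the log2 scale (SE, 3 kainate against 6 control arrays, limma adjusted p = 1.49e-13), for a probe detected on 2 of the 6 controls, so that its size rests on a control level near background. Fos (ILMN_2750515) rose by 6.02 ± 0.19 (65.1-fold), and Npas4 (ILMN_1251414), which drives inhibitory synapse genes in active neurons, by 5.56 ± 0.09 (47.3-fold). Egr4 (ILMN_1215713), Junb (ILMN_1220034) and the cyclin gene Ccno (ILMN_2736471) rose by 5.3 ± 0.3, 5.14 ± 0.16 and 4.45 ± 0.14. The largest fall was that of Nxph2 (ILMN_1251624), which encodes a secreted ligand of neurexins, at -2.6 ± 0.1 (adjusted p = 1.16e-11). The relaxin-3 receptor gene Rxfp3 (ILMN_1240943) changed by -2.03 ± 0.14, Cdc42ep2 (ILMN_1239294) by -1.95 ± 0.1, the receptor gene Gpr17 (ILMN_3160970) by -1.91 ± 0.1, Larp6 (ILMN_1219564) by -1.86 ± 0.11 and the neuropeptide gene Cort (ILMN_1226607) by -1.76 ± 0.19. Of 14154 probes tested, 5474 changed (38.7%), 2534 higher and 2940 lower, and 2123 of these by 1.5-fold or more. The changed probes named 4355 genes.

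Immediate early and activity-regulated genes rose as a group at 5 h. Of 36 measured, 31 rose, 0 fell and 5 did not pass, with the same 31 and 0 adjusted over the list alone. Their median change was 2.28 (camera adjusted p = 4.17e-30, and adjusted p = 2.4e-06 with an estimated correlation). Gadd45g (ILMN_2744890), a stress and activity gene acting in DNA demethylation, rose by 3.76 ± 0.13, and Maff (ILMN_1256996), a small Maf factor, by 2.86 ± 0.07. Cell cycle and DNA replication genes rose next, 32 of 47 rising, 2 falling and 13 not passing (32 and 2 adjusted over the list alone), with a median of 0.63 (adjusted p = 7.76e-09, but adjusted p = 0.191 with an estimated correlation). Top2a (ILMN_1214399), the topoisomerase of dividing cells, rose 2.37-fold, the ribonucleotide reductase gene Rrm1 (ILMN_1258715) by 0.91 ± 0.1 and the replication helicase gene Mcm2 (ILMN_1250907) by 0.89 ± 0.08.

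NRF2, lysosome, inflammatory, ATF4, growth factor and ribosomal genes rose as lists at 5 h, each call lost with an estimated correlation, while the unfolded protein response, heat shock and p53 lists did not pass (adjusted p = 0.556, 0.17 and 0.32). Among NRF2 targets, 16 of 34 rose, 3 fell and 15 did not pass (18 and 3 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.00109, adjusted p = 0.175 with an estimated correlation). Srxn1 (ILMN_1212763), which repairs oxidised peroxiredoxins, rose by 1.65 ± 0.08. Lysosome and autophagy genes had 11 of 33 rising and 3 falling, also adjusted over the list alone, at a median of 0.15 (adjusted p = 0.0296, adjusted p = 0.0938 with an estimated correlation). The alpha-galactosidase gene Gla (ILMN_2626086), detected on none of the controls, was at least 3.81-fold higher. Of 22 inflammatory genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), at a median of 0.18 (adjusted p = 0.0296, adjusted p = 0.351 with an estimated correlation). The TWEAK receptor gene Tnfrsf12a (ILMN_2424299) rose by 1.68 ± 0.1. ATF4 targets had 10 of 32 rising and 3 falling (11 and 4 adjusted over the list alone), at a median of 0.23 (adjusted p = 0.0296, adjusted p = 0.844 with an estimated correlation). Ppp1r15a (ILMN_2722938), which restores translation after stress, rose by 2.59 ± 0.14 and Atf3 (ILMN_2619408) by 2.56 ± 0.14, while the secreted factor gene Stc2 (ILMN_2739544) changed by -0.65 ± 0.11. Growth factor genes had 12 of 30 rising and 3 falling (14 and 3 adjusted over the list alone), at a median of 0.19 (adjusted p = 0.0173, adjusted p = 0.0708 with an estimated correlation). Igfbp2 (ILMN_1236788), a binding protein gene, rose by 0.93 ± 0.09. Ribosomal protein genes had 10 of 31 rising and 0 falling, also adjusted over the list alone, at a median of 0.19 (adjusted p = 0.0231, adjusted p = 0.595 with an estimated correlation).

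Of 7 marker lists of cell types other than neurons, the astrocyte, progenitor and fibroblast lists moved up at 5 h. Of 15 astrocyte markers 8 rose and 1 fell (10 and 1 adjusted over the list alone), at a median of 0.39 (adjusted p = 0.00761, adjusted p = 0.0708 with an estimated correlation). Gfap (ILMN_1214715), the astrocyte intermediate filament gene, rose by 0.72 ± 0.1. Of 15 neural progenitor markers 7 rose and 0 fell, also adjusted over the list alone, at a median of 0.28 (adjusted p = 0.00293, adjusted p = 0.191 with an estimated correlation), led by the vimentin gene Vim (ILMN_3161394), which rose 2.79-fold. Of 12 fibroblast markers 5 rose and 0 fell, also adjusted over the list alone, at a median of 0.24 (adjusted p = 0.0367, adjusted p = 0.191 with an estimated correlation). The matrix gene Fbln2 (ILMN_1245307) rose by 1.1 ± 0.11. The other 4 lists did not shift. Among microglia markers 0 of 11 rose and 2 fell (0 and 1 adjusted over the list alone, median -0.15, adjusted p = 0.485). Among oligodendrocyte markers 1 of 11 rose and 3 fell (2 and 3 adjusted over the list alone, median 0.13, mean -0.18, adjusted p = 0.755). Of 7 endothelial and 3 erythroid genes 0 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.715 and 0.908). The fibroblast call was lost without control replicate 1 (0.24), without control replicate 3 (0.23) and without 5 h replicate 3 (0.34).

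The 5 h lists depend on control replicates 1 and 3, whose levels lay nearer to the 5 h arrays for several lists. With these controls and the 5 h arrays as a block against the other 10 arrays, 4568 probes changed at 5 h. Of the 5474, 3656 changed again in the same direction, with 0 opposite. In that fit the 5 h effect rests on control replicates 1 and 3 alone and the later effects on the other 4 controls. It presumes that the 5 h arrays share what sets those 2 controls apart, which was not tested. With the block the ATF4, inflammatory and ribosomal lists lost their calls, at medians of -0.14, 0.11 and 0.05. The glycolysis (0.26) and cholesterol (0.22) lists gained calls upward, both also with an estimated correlation (adjusted p = 0.0456). The other 8 lists kept their calls, with medians of 0.25 for cell cycle, 0.17 for NRF2, 0.17 for progenitor and 0.38 for growth factor genes. With an estimated correlation in that fit, NRF2, progenitor and growth factor genes did not pass (adjusted p = 0.139, 0.184 and 0.0559) and the other 5 lists did. The ATF4 call was also lost without control replicate 2 (0.18), 4 (0.16) or 5 (0.18). Without control replicates 1 and 3 altogether, 6372 probes changed, the fibroblast list (0.22) and the lysosome list (0.18) lost their calls, and the oxidative phosphorylation list (0.21) gained a call upward and the cholesterol list (-0.38) a call downward, opposite to its direction with the block. The share of higher calls at 5 h was 46.3%, against 61.8% after median centring and 59.4% in the authors' ratios.

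**Figure D1:**
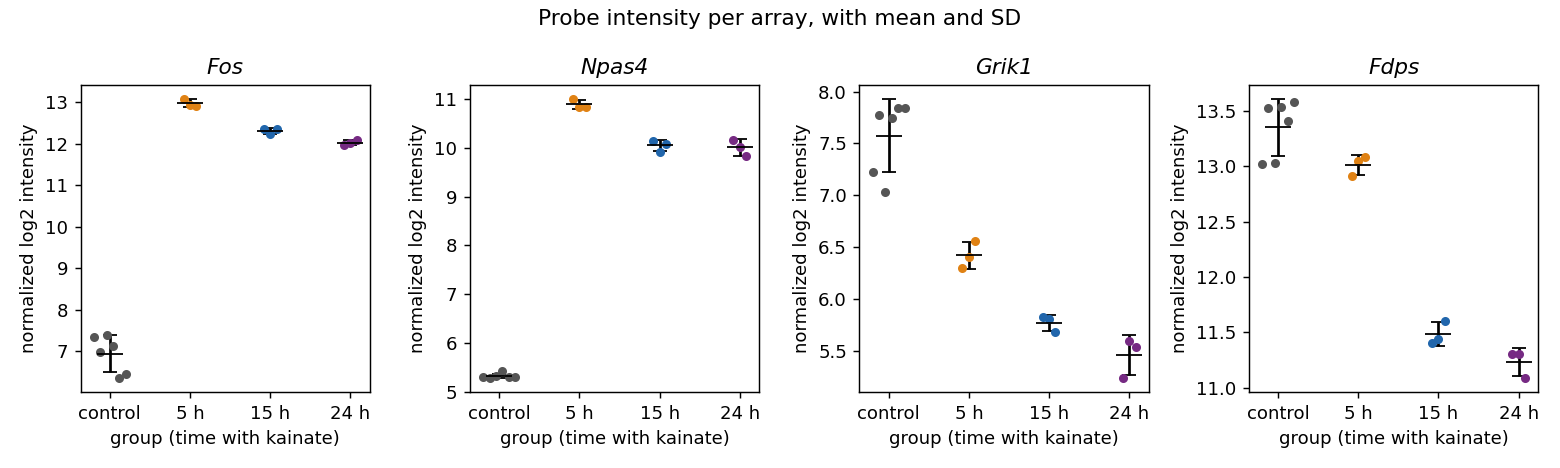
Normalized log2 intensity (vertical axis) of the probes of Fos, Npas4, Grik1 and Fdps in the controls and after 5 h, 15 h and 24 h with kainate (horizontal axis). Dots are arrays, with the mean and SD of each group, and Fos and Npas4 lay above the controls at every time (6.02 and 5.56 at 5 h), Grik1 below them (-2.12 at 24 h) and Fdps below them from 15 h (-1.87).

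At 15 h the neuropeptide and synaptic genes Npy, Nxph2 and Cbln1 fell while immediate early genes stayed high. Fos, Npas4 and Fosb were still higher by 5.36, 4.72 and 4.69, and Gadd45g by 4.39 ± 0.13. Angptl4 (ILMN_2759365), an inhibitor of lipoprotein lipase, rose by 3.94 ± 0.11 (15.3-fold, limma adjusted p = 7e-13) and Csrnp1 (ILMN_2636403), a nuclear factor of the Axin pathway, by 3.73 ± 0.13. The largest falls were Nxph2 at -4.85 ± 0.1, with a detected signal on 1 of 3 arrays, the neuropeptide Y gene Npy (ILMN_1243928) at -2.83 ± 0.11 (adjusted p = 1.62e-11), Lor (ILMN_1241825) at -2.8 ± 0.09, the synaptic organiser gene Cbln1 (ILMN_1252953) at -2.5 ± 0.11, Lin7b (ILMN_1260389) at -2.38 ± 0.1 and Cort at -2.32 ± 0.19. In all, 6410 probes changed (45.3%), 3090 higher and 3320 lower, naming 4926 genes. A change of 1.5-fold or more was seen in 3116 of them.

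The presynaptic, cytoskeleton and calcium lists went down at 15 h, while 5 other neuronal lists did not pass. Of 32 presynaptic genes 4 rose, 22 fell and 6 did not pass, also adjusted over the list alone, with a median of -0.57 (adjusted p = 0.000478, but adjusted p = 0.215 with an estimated correlation). Doc2b (ILMN_2736478), a calcium sensor of vesicle release, changed by -2.23 ± 0.15, Rph3a (ILMN_2595600) by -1.78 ± 0.16 and the syntaxin gene Stx1a (ILMN_2700608) by -1.15 ± 0.09. In the neuronal cytoskeleton and axon growth list 1 of 31 rose and 16 fell, also adjusted over the list alone, at a median of -0.36 (adjusted p = 0.000478, adjusted p = 0.205 with an estimated correlation). Tubb3 (ILMN_2466818), the neuronal tubulin gene, changed by -1.31 ± 0.12 and Crmp1 (ILMN_1244675), a mediator of semaphorin signals, by -1.3 ± 0.08. Calcium channel, pump and buffer genes had 0 of 23 rising and 14 falling (0 and 15 adjusted over the list alone), at a median of -0.42 (adjusted p = 0.00147, adjusted p = 0.408 with an estimated correlation). The calcium sensor genes Hpca (ILMN_2635114) and Vsnl1 (ILMN_2438724) changed by -1.46 ± 0.12 and -1.13 ± 0.12. Cholesterol biosynthesis genes fell further than any of these lists, 17 of 26 falling and 2 rising (18 and 2 adjusted over the list alone), with a median of -0.93 (adjusted p = 2.34e-05, adjusted p = 0.43 with an estimated correlation). The mevalonate kinase gene Mvk (ILMN_1239601) changed by -2.16 ± 0.15, the farnesyl diphosphate synthase gene Fdps (ILMN_1225730) by -1.87 ± 0.13 and the sterol reductase gene Tm7sf2 (ILMN_1241333) by -1.28 ± 0.09. With control replicates 1 and 3 and the 5 h arrays as a block, the presynaptic, cytoskeleton, calcium and cholesterol medians were -0.64, -0.45, -0.63 and -1.25, and all 4 passed with an estimated correlation (adjusted p = 0.00494, 0.0456, 0.0305 and 0.00027). That fit sets 15 h against the other 4 controls, since replicates 1 and 3 scored low on the presynaptic, calcium and cholesterol lists. It also takes their difference out of the spread that gives the correlation. These p-values are therefore no independent support, as for every list at 15 h and 24 h with this block.

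Progenitor, astrocyte and microglia markers were higher than in the controls at 15 h. The neural progenitor list had 14 of 15 rising and 0 falling, also adjusted over the list alone, at a median of 0.62 (adjusted p = 3.87e-06, adjusted p = 0.0639 with an estimated correlation). Vim rose by 1.67 ± 0.08, the endothelin receptor gene Ednrb (ILMN_2589640) by 1.52 ± 0.08 and Notch1 (ILMN_1241915) by 1.44 ± 0.13. The astrocyte list had 8 of 15 rising and 0 falling (8 and 1 adjusted over the list alone), at a median of 0.71 (adjusted p = 0.000885, and adjusted p = 0.0351 with an estimated correlation). Its gap junction gene Gja1 (ILMN_1244291) rose by 1.74 ± 0.1, Gfap by 1.73 ± 0.1 and the apolipoprotein gene Apoe (ILMN_1216042) by 1.35 ± 0.09. Of 11 microglia markers 6 rose and 1 fell, also adjusted over the list alone, at a median of 0.52 (adjusted p = 0.0356, adjusted p = 0.318 with an estimated correlation). The galectin gene Lgals3 (ILMN_1223317) rose by 1.59 ± 0.15. The microglia call was lost without 15 h replicate 3 (0.45), without control replicates 1 and 3 (0.48) and with the block of 5 arrays (0.48). With the block, the progenitor and astrocyte lists passed with an estimated correlation (adjusted p = 0.0158 and 0.0263).

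Several defence and stress lists rose at 15 h. Among all lists, 8 passed upward at 15 h with the beadchip as a random block, against 13 without it. The random block was tested with cameraPR instead of camera, so the model and the test changed together. With a fixed block for the beadchip 13 passed upward. The lists that lost their calls with the random block are not named here. NRF2 targets had 22 of 34 rising and 6 falling (23 and 6 adjusted over the list alone), at a median of 0.4 (adjusted p = 0.000478, adjusted p = 0.121 with an estimated correlation). The detoxification genes Ephx1 (ILMN_2664224) and Gsta4 (ILMN_2773022) rose by 1.4 ± 0.08 and 1.4 ± 0.1. Interferon response genes had 11 of 20 rising and 1 falling, also adjusted over the list alone, at a median of 0.4 (adjusted p = 0.00306, adjusted p = 0.205 with an estimated correlation). The class I light chain gene B2m (ILMN_2740000) rose by 1.36 ± 0.1. Inflammatory genes had 10 of 22 rising and 0 falling, also adjusted over the list alone, at a median of 0.25 (adjusted p = 0.00668, adjusted p = 0.205 with an estimated correlation). The adhesion gene Vcam1 (ILMN_1258714) rose by 1.33 ± 0.14 and Stat3 (ILMN_2589790) by 1.11 ± 0.16. Lysosome genes had 18 of 33 rising and 4 falling, also adjusted over the list alone, at a median of 0.25 (adjusted p = 0.0102, adjusted p = 0.0639 with an estimated correlation). Lamp2 (ILMN_1217454) and Cd63 (ILMN_2653618), both of the lysosomal membrane, rose by 1.34 ± 0.09 and 1.34 ± 0.1. Calpain and cathepsin genes had 10 of 19 rising and 3 falling, also adjusted over the list alone, at a median of 0.34 (adjusted p = 0.0338, adjusted p = 0.121 with an estimated correlation). The protease inhibitor gene Serpina3n (ILMN_1246800) rose by 1.44 ± 0.09 and the calpain gene Capn5 (ILMN_2627566) changed by -0.9 ± 0.1. Of 25 p53 targets 9 rose and 2 fell, also adjusted over the list alone, at a median of 0.2 (adjusted p = 0.0356, adjusted p = 0.173 with an estimated correlation), led by the death gene Pmaip1 (ILMN_2670625), detected on 2 of the 6 controls, at 2.76 ± 0.22.

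The immediate early list moved furthest up at 15 h. It had 33 of 36 rising and 0 falling, also adjusted over the list alone, at a median of 1.9 (adjusted p = 2.78e-22, and adjusted p = 1.14e-05 with an estimated correlation). Cell cycle genes had 15 of 47 rising and 3 falling, also adjusted over the list alone, at a median of 0.28 (adjusted p = 0.0155, adjusted p = 0.453 with an estimated correlation). E2f1 (ILMN_1231138), a factor for S-phase entry, changed by -0.66 ± 0.07 after rising by 0.4 ± 0.07 at 5 h. Growth factor genes had 13 of 30 rising and 5 falling (14 and 5 adjusted over the list alone), at a median of 0.2 (adjusted p = 0.0155, adjusted p = 0.0651 with an estimated correlation). The neuropeptide gene Adcyap1 (ILMN_1227605) rose by 1.72 ± 0.1. Ribosomal protein genes had 11 of 31 rising and 1 falling, also adjusted over the list alone, at a median of 0.22 (adjusted p = 0.0228, adjusted p = 0.439 with an estimated correlation). After median centring the lysosome (0.12), ribosomal (0.15), calpain (0.25) and p53 (0.14) lists lost their calls at 15 h. The calpain (0.25) and p53 (0.22) calls were also lost without 15 h replicate 3, and the p53 call without control replicate 1 (0.19). With the block of 5 arrays both were lost, at 0.37 and 0.2. With an estimated correlation in that fit, cell cycle, NRF2, lysosome and ribosomal genes passed (adjusted p = 0.00574, 0.0456, 0.0456 and 0.0217). Interferon, inflammatory and growth factor genes did not (adjusted p = 0.174, 0.0593 and 0.154).

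At 24 h the changes were close to those at 15 h. Fos, Npas4, Gadd45g, Fosb and Angptl4 were higher by 5.08, 4.68, 4.58, 4.22 and 3.92, and Rnf138rt1 (ILMN_2597397) by 3.8 ± 0.16. Nxph2, detected on none of the 3 arrays, was at least 27.6-fold lower. Npy changed by -3.49 ± 0.11 (11.3-fold lower, limma adjusted p = 1.23e-12), Lor by -2.92, Cbln1 by -2.76, the cholesterol gene Nsdhl (ILMN_2594525) by -2.64 ± 0.2 and the matrix gene Dcn (ILMN_2716756) by -2.54 ± 0.11. In all, 6087 probes changed (43%), 2989 higher and 3098 lower, naming 4688 genes, and 2868 changed by 1.5-fold or more. Another scaling moves this balance. The share of higher calls was 49.1%, but 22.4% after median centring, 25.4% in the authors' ratios and 59.4% after centring on probes detected on all arrays, where the median of all probes stood at -0.193, -0.114 and 0.114.

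Of the lists at 24 h, cholesterol biosynthesis moved furthest down, 19 of 26 genes falling and 2 rising, also adjusted over the list alone, at a median of -1.11 (adjusted p = 6.92e-07, adjusted p = 0.33 with an estimated correlation). Mvk, Fdps and Tm7sf2 changed by -2.24, -2.12 and -1.63. Presynaptic genes had 21 of 32 falling and 4 rising (21 and 5 adjusted over the list alone), at a median of -0.52 (adjusted p = 0.000511, adjusted p = 0.253 with an estimated correlation). Doc2b and the vesicle gene Syngr1 (ILMN_2652711) changed by -2.09 ± 0.15 and -1.09 ± 0.12. The cytoskeleton list had 18 of 31 falling and 1 rising (20 and 2 adjusted over the list alone), at a median of -0.44 (adjusted p = 0.000244, adjusted p = 0.244 with an estimated correlation). The calcium list had 13 of 23 falling and 0 rising, also adjusted over the list alone, at a median of -0.42 (adjusted p = 0.00534, adjusted p = 0.333 with an estimated correlation). Hpca, a calcium sensor gene of that list, changed by -1.75 ± 0.12. With control replicates 1 and 3 and the 5 h arrays as a block, the cholesterol, presynaptic, cytoskeleton and calcium medians at 24 h were -1.39, -0.56, -0.5 and -0.61. With an estimated correlation in that fit, the cytoskeleton list did not pass (adjusted p = 0.0507) and the other 3 did (adjusted p = 0.000121, 0.00535 and 0.0426). As at 15 h, the fit sets aside control replicates 1 and 3, which scored low on these 3 lists. The lower p-values are therefore no independent support.

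Upward at 24 h, the immediate early list had 32 of 36 rising and 0 falling, also adjusted over the list alone, at a median of 2.07 (adjusted p = 9.69e-22, and adjusted p = 1.29e-05 with an estimated correlation). Neural progenitor markers had 11 of 15 rising and 0 falling (12 and 0 adjusted over the list alone), at a median of 0.68 (adjusted p = 3.65e-05, adjusted p = 0.107 with an estimated correlation), with Ednrb at 1.43 ± 0.08 and Vim at 1.36 ± 0.08. Astrocyte markers had 7 of 15 rising and 1 falling, also adjusted over the list alone, at a median of 0.54 (adjusted p = 0.00732, adjusted p = 0.0919 with an estimated correlation), with Gfap at 1.63 ± 0.1. Growth factor genes had 13 of 30 rising and 3 falling, also adjusted over the list alone, at a median of 0.41 (adjusted p = 0.0157, adjusted p = 0.0919 with an estimated correlation), with Adcyap1 at 2.32 ± 0.1. Interferon genes had 9 of 20 rising and 1 falling, also adjusted over the list alone, at a median of 0.3 (adjusted p = 0.0271, adjusted p = 0.322 with an estimated correlation). Inflammatory genes had 10 of 22 rising and 1 falling (11 and 1 adjusted over the list alone), at a median of 0.27 (adjusted p = 0.0271, adjusted p = 0.308 with an estimated correlation). Without 24 h replicate 3 the interferon (0.18) and inflammatory (0.22) calls were lost. NRF2 targets had 17 of 34 rising and 6 falling (18 and 6 adjusted over the list alone), at a median of 0.35 (adjusted p = 0.00732, adjusted p = 0.246 with an estimated correlation), with Ephx1 at 1.02 ± 0.08. Lysosome genes had 16 of 33 rising and 4 falling, also adjusted over the list alone, at a median of 0.25 (adjusted p = 0.0343, adjusted p = 0.107 with an estimated correlation). Ribosomal genes had 16 of 31 rising and 1 falling, also adjusted over the list alone, at a median of 0.24 (adjusted p = 0.00534, adjusted p = 0.333 with an estimated correlation). These last 3 lists depended on the scaling at 24 h, with medians of 0, -0.15 and -0.05 after median centring and no call there. With the block of 5 arrays the lysosome call was lost (0.28), the growth factor median was 0.27, and the cell cycle list, not called without the block, passed upward (0.42, adjusted p = 0.0162 with an estimated correlation). With an estimated correlation there, progenitor and ribosomal genes passed (adjusted p = 0.0246 and 0.0107). Astrocyte, NRF2, lysosome, inflammatory, interferon and growth factor genes did not (adjusted p = 0.0561, 0.0984, 0.0984, 0.0986, 0.254 and 0.116).

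Kainate acts through ionotropic glutamate receptors, and the kainate receptor subunit gene Grik1 (ILMN_1243701) fell at every time. It changed by -1.15 ± 0.17 at 5 h, -1.8 ± 0.17 at 15 h and -2.12 ± 0.17 at 24 h (limma adjusted p = 5.28e-05, 2.41e-07 and 4.83e-08). The AMPA receptor subunit gene Gria1 (ILMN_1248802) changed by -1 ± 0.26 at 15 h and did not pass at 5 h (-0.39). At 24 h it passed again (adjusted p = 0.000221). Neto1 (ILMN_2620827), which encodes an auxiliary subunit of kainate receptors, changed by -1.47 ± 0.2 at 15 h and -1.57 ± 0.2 at 24 h. Gria2 (ILMN_1236513), whose subunit makes AMPA receptors impermeable to calcium, did not pass at any time, at -0.14, -0.34 and -0.16. For Gria2 at 5 h the value turned to 0.27 with the block of 5 arrays, and Gria2 at 15 h and Gria2 at 24 h passed after median centring, at -0.55 and -0.64. The NMDA receptor subunit genes Grin2b (ILMN_2617353), detected on 1 of the 6 controls, and Grin2c (ILMN_2757485) rose at 24 h by 0.55 ± 0.16 and 0.69 ± 0.17. Grin2b at 24 h was lost without 24 h replicate 3, at 0.33. Gria3 (ILMN_2638066) rose at 15 h by 0.49 ± 0.17, but another probe of that gene fell, and neither Grik4 (ILMN_1232802), Grik5 (ILMN_2483633) nor Grin3b (ILMN_1229979) passed at any time. As a list, 2 of 13 receptor and auxiliary subunit genes rose and 2 fell at 5 h (the same adjusted over the list alone), 3 rose and 5 fell at 15 h (3 and 6 adjusted over the list alone), and 2 rose and 5 fell at 24 h (4 and 6 adjusted over the list alone). The list did not shift against the controls (adjusted p = 0.908, 0.386 and 0.234). With the block of 5 arrays it passed downward from 5 h to 15 h (-0.78) and from 5 h to 24 h (-0.63), but not with an estimated correlation (adjusted p = 0.137 and 0.0892).

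**Figure D2:**
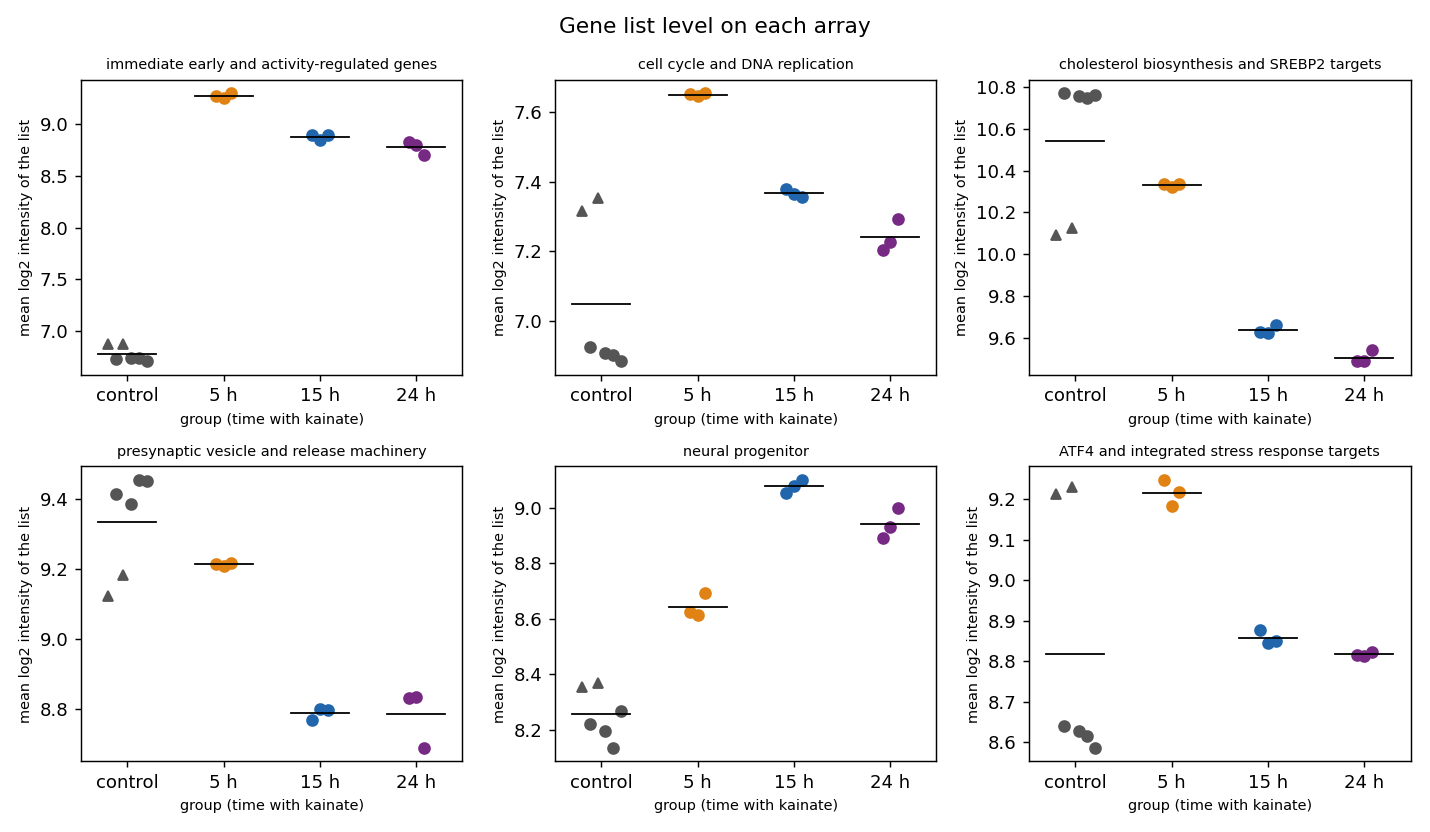
Mean log2 intensity of the measured genes of 6 gene lists (vertical axis) on each array of the controls and of the 5 h, 15 h and 24 h groups (horizontal axis). Marks are arrays, triangles are control replicates 1 and 3 and bars are group means. Cholesterol scores at 15 h and 24 h (9.49 to 9.66) lay below all controls (10.09 to 10.77), and control replicates 1 and 3 lay with the 5 h arrays in the ATF4 panel.

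Between 5 h and 15 h, cholesterol, presynaptic, cytoskeleton and calcium genes fell as lists while microglia and progenitor markers rose. Bdh2 (ILMN_2641678), a dehydrogenase gene of siderophore and ketone metabolism, rose by 2.68, the iron exporter gene Slc40a1 (ILMN_2747923) by 2.5 and the Fc receptor gene Fcgrt (ILMN_2773706) by 2.4 (limma adjusted p = 9.91e-09, 1.46e-06 and 5.07e-08, SE of the model for 3 against 3 arrays at a median of 0.14). Fosb changed by -2.64, Npy by -2.63 and Lor by -2.52. In all, 4672 probes changed, 2411 higher and 2261 lower. The share of higher calls was 51.6%, but 27.1% after median centring and 29.9% in the authors' ratios. Cholesterol genes had 14 of 26 falling and 0 rising (14 and 1 adjusted over the list alone), at a median of -0.72 (adjusted p = 3.88e-05, adjusted p = 0.599 with an estimated correlation). The cytoskeleton list had 17 of 31 falling and 2 rising (18 and 2 adjusted over the list alone), at -0.47 (adjusted p = 0.000124, adjusted p = 0.462 with an estimated correlation), and the presynaptic list had 11 of 32 falling and 0 rising (12 and 0 adjusted over the list alone), at -0.23 (adjusted p = 0.000907, adjusted p = 0.493 with an estimated correlation). Calcium genes had 9 of 23 falling and 1 rising, also adjusted over the list alone, at -0.29 (adjusted p = 0.00549, adjusted p = 0.599 with an estimated correlation). Immediate early genes had 16 of 36 falling and 4 rising (16 and 5 adjusted over the list alone), at -0.27 (adjusted p = 0.00631, adjusted p = 0.17 with an estimated correlation). Microglia markers had 6 of 11 rising and 0 falling (7 and 0 adjusted over the list alone), at 0.49 (adjusted p = 0.00734, adjusted p = 0.462 with an estimated correlation). Laptm5 (ILMN_1217849), a lysosomal gene of blood-derived cells, rose by 1.86. Progenitor markers had 5 of 15 rising and 0 falling, also adjusted over the list alone, at 0.24 (adjusted p = 0.0112, adjusted p = 0.493 with an estimated correlation).

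Another 3 lists moved down from 5 h to 15 h only without the block of control replicates 1 and 3 with the 5 h arrays. Cell cycle genes had 13 of 47 falling and 2 rising, also adjusted over the list alone, at -0.32 (adjusted p = 0.00228, adjusted p = 0.599 with an estimated correlation), but 0.09 with the block. ATF4 targets had 9 of 32 falling and 1 rising, also adjusted over the list alone, at -0.29 (adjusted p = 0.00696, adjusted p = 0.599 with an estimated correlation), but 0.33 with the block. Oxidative phosphorylation genes had 10 of 46 falling and 1 rising (9 and 1 adjusted over the list alone), at -0.15 (adjusted p = 0.014, adjusted p = 0.599 with an estimated correlation), but 0.06 with the block. Its ATP synthase gene Atp5k (ILMN_2776900) changed by -1.37. The immediate early list kept its direction with the block, at -0.3, but lost its call. Medians of other lists grew with the block, to -0.81 for calcium, -0.55 for presynaptic, -1.54 for cholesterol and 0.52 for progenitor genes. By construction this contrast then takes in the difference of control replicates 1 and 3 from the other controls. That the 5 h arrays share this difference was not tested. The calcium, presynaptic, cholesterol and cytoskeleton lists then passed with an estimated correlation (adjusted p = 0.0264, 0.00198, 4.43e-05 and 0.0448), and the progenitor list did not (adjusted p = 0.124). In that fit 4536 probes changed from 5 h to 15 h, 3034 of them shared with the 4672 in the same direction and 1 in the opposite.

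From 15 h to 24 h, 86 probes changed, a count that depended strongly on the model. The ubiquitin ligase gene Mid1 (ILMN_2619452) rose by 1.39 (limma adjusted p = 0.00117), the muscle M-band gene Myom2 (ILMN_1238982), detected on none of the 15 h arrays, was at least 1.77-fold higher, and Gpr17 rose by 0.96 (adjusted p = 0.00169). The desaturase gene Scd1 (ILMN_1237375) changed by -1.02 (adjusted p = 0.00169) and Atf3 by -0.98 (adjusted p = 0.0151), while Atoh7 (ILMN_1247770), detected on none of the 24 h arrays, was at least 1.53-fold lower. Of the 86, 30 were higher and 56 lower, with 1928 at an unadjusted p below the same threshold. After median centring 11 of 391 were higher, and in the authors' ratios 7 of 505. Replicate 3 at 24 h stood apart from the other 24 h arrays. The 24 h effects on its beadchip correlated across probes at 0.641 and 0.692 with those on the other beadchips, which correlated at 0.888. At 15 h the lowest such value was 0.86. The count of 86 therefore does not by itself show the 2 times to be alike. The number of probes changed from 15 h to 24 h moved with the model and with single arrays. It was 1800 with array weights and 1887 without control replicates 1 and 3 and 24 h replicate 3. It was 640 without 24 h replicate 3, 18 and 10 without 24 h replicates 1 and 2, 12, 7 and 9 without each array at 15 h, 44, 42 and 47 without each array at 5 h, and 56 without control replicate 4. Oligodendrocyte markers moved up (2 of 11 rising and 0 falling, 3 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.0226, adjusted p = 0.147 with an estimated correlation). Neural progenitor markers moved down without a single member passing (0 and 4 adjusted over the list alone, median -0.16, adjusted p = 0.0479, adjusted p = 0.475 with an estimated correlation), and NRF2 targets also moved down (0 of 34 rising and 1 falling, 0 and 5 adjusted over the list alone, median -0.06, adjusted p = 0.0257, adjusted p = 0.34 with an estimated correlation). Without 24 h replicate 3 all 3 of these calls were lost, at 0.24, -0.11 and -0.09. The NRF2 call was also lost without 15 h replicate 3 (-0.08). The progenitor call was also lost without control replicates 2, 3 or 6 or 5 h replicate 1 (-0.16 each), 15 h replicate 2 (-0.13), 15 h replicate 3 (-0.14) or 24 h replicate 1 (-0.14).

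From 5 h to 24 h the same neuronal and sterol lists moved as from 5 h to 15 h. Cholesterol genes had 15 of 26 falling and 0 rising (16 and 0 adjusted over the list alone), at a median of -0.95 (limma adjusted p = 1.78e-06, adjusted p = 0.542 with an estimated correlation). Presynaptic genes had 14 of 32 falling and 3 rising (16 and 4 adjusted over the list alone), at -0.35 (adjusted p = 0.000611, adjusted p = 0.502 with an estimated correlation). Cytoskeleton genes had 16 of 31 falling and 2 rising (18 and 2 adjusted over the list alone), at -0.45 (adjusted p = 6.1e-05, adjusted p = 0.395 with an estimated correlation). Immediate early genes changed by a median of -0.35 (adjusted p = 0.000945, adjusted p = 0.0613 with an estimated correlation), with 17 of 36 falling and 5 rising, also adjusted over the list alone, and microglia markers by 0.66 (adjusted p = 0.0139, adjusted p = 0.502 with an estimated correlation), with 6 of 11 rising and 0 falling (6 and 1 adjusted over the list alone). Calcium genes had 7 of 23 falling and 2 rising (8 and 2 adjusted over the list alone), at -0.21 (adjusted p = 0.0189, adjusted p = 0.674 with an estimated correlation), a call lost without 24 h replicate 3 (-0.17). Cell cycle genes had 18 of 47 falling and 1 rising, also adjusted over the list alone, at -0.35 (adjusted p = 6.1e-05, adjusted p = 0.542 with an estimated correlation). ATF4 targets had 11 of 32 falling and 1 rising, also adjusted over the list alone, at -0.32 (adjusted p = 0.00582, adjusted p = 0.707 with an estimated correlation). These last calls were lost with the block of 5 arrays, at 0.02 and 0.2. With the block the cholesterol, presynaptic and calcium medians grew to -1.85, -0.74 and -0.89, and passed with an estimated correlation (adjusted p = 2.77e-05, 0.00231 and 0.039). As from 5 h to 15 h, the difference of control replicates 1 and 3 from the other controls then enters the contrast. In all, 5038 probes changed, 2633 higher and 2405 lower, and 4599 with the block. The share of higher calls was 52.3%, but 12.4% after median centring, 14.9% in the authors' ratios and 66.4% after centring on probes detected on all arrays.

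Shared changes were most numerous between 15 h and 24 h, where 2396 probes were higher and 2530 lower at both times and 7 went opposite ways. Independent lists of these sizes would share 653 and 727. Fold changes at these times correlated at 0.931 across probes, which are not independent replicates, against 0.333 for simulated unchanged groups with the same controls (covariance 0.287 against 0.0071). With controls split into odd and even numbers, which keeps control replicates 1 and 3 together, the correlation was 0.856. Over all 20 splits into sets of 3 it was 0.801 to 0.918. The same splits gave 0.532 to 0.623 for 5 h and 15 h, and 0.464 to 0.583 for 5 h and 24 h. Between 5 h and 15 h, 1490 probes were higher and 1591 lower at both times, against 553 and 690 for independent lists, with a correlation of 0.64 (simulated 0.335, covariance 0.174 against 0.0071, and 0.571 with separate controls). Opposite calls numbered 274, of which 131 were higher and then lower, as for E2f1 and the collapsin response gene Crmp1 (0.36 ± 0.08 at 5 h), and 143 lower and then higher, as for the microglial gene Laptm5 (-0.82 ± 0.17 at 5 h and 1.04 ± 0.17 at 15 h). Between 5 h and 24 h, 1379 probes were higher and 1454 lower at both times, against 535 and 644 for independent lists, with 306 opposite and a correlation of 0.593 (simulated 0.335, covariance 0.155 against 0.0071, and 0.521 with separate controls). By the F test, 8665 probes changed at any time (61.2%).

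The excitatory, postsynaptic, GABAergic and voltage-gated channel lists did not pass against the controls, although many members changed, and for each this call turned under some alternatives. Excitatory neuron markers had 3 of 15 rising and 9 falling at 15 h (3 and 10 adjusted over the list alone, median -0.41, adjusted p = 0.0793), with the vesicular transporter gene Slc17a6 (ILMN_2773047) at -0.68 ± 0.09 and the layer gene Cux2 (ILMN_1234471) at 1.08 ± 0.11. Postsynaptic genes had 4 of 23 rising and 13 falling at 15 h, also adjusted over the list alone (median -0.3, adjusted p = 0.0758), with the scaffold genes Dlg3 (ILMN_2766622) at -1.06 ± 0.11 and Dlg2 (ILMN_1253174) at 1.38 ± 0.07. Without 24 h replicate 1 this list passed at 24 h (-0.4), and with the block of 5 arrays at 15 h (-0.36) and 24 h (-0.5), though not with an estimated correlation in that fit (adjusted p = 0.366 and 0.345). GABAergic genes had 3 of 14 rising and 7 falling at 15 h (3 and 8 adjusted over the list alone, median -0.45, adjusted p = 0.174), with the vesicular GABA transporter gene Slc32a1 (ILMN_1234039) at -1.37 ± 0.09. The parvalbumin gene Pvalb (ILMN_1218223), detected on none of the controls, was at least 2.46-fold higher at 15 h. Voltage-gated channel genes had 6 of 22 rising and 7 falling (6 and 8 adjusted over the list alone, median -0.2, adjusted p = 0.386), with the potassium channel genes Kcnab1 (ILMN_1216469) at -1.9 ± 0.19 and Kcnk1 (ILMN_2777530) at -1.01 ± 0.11. With the block the channel list passed at 24 h (-0.35), but had adjusted p = 0.0637 with an estimated correlation. The excitatory list passed at 15 h with no filter (-0.41), and the GABAergic list at 24 h with trend and robust (-0.36), tested with cameraPR.

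Cell death and protein quality lists went both ways. Apoptosis genes had 6 of 30 rising and 12 falling at 15 h, also adjusted over the list alone (median -0.14, adjusted p = 0.386), with Casp6 (ILMN_2711604) at 1.27 ± 0.09, Casp9 (ILMN_1217061) at -0.57 ± 0.12 and the death gene Hrk (ILMN_1229407) at -0.71 ± 0.12. Heat shock genes had 10 of 28 rising and 2 falling, also adjusted over the list alone (median -0.02, mean 0.25, adjusted p = 0.156 for an upward shift), with the chaperone genes Hspb8 (ILMN_2761205) and Hspa2 (ILMN_1223285) at 1.69 ± 0.14 and 1.63 ± 0.09. Unfolded protein response genes had 7 of 23 rising and 3 falling, also adjusted over the list alone (median 0.14, adjusted p = 0.386), with Wfs1 (ILMN_1224079) at -0.98 ± 0.17. Proteasome genes had 1 of 33 rising and 5 falling (0 and 2 adjusted over the list alone, median -0.05, adjusted p = 0.386), with Psmb5 (ILMN_2613469) at -0.28 ± 0.08. Glycolysis genes had 7 of 22 rising and 6 falling (7 and 7 adjusted over the list alone, median -0.1, mean 0.12, adjusted p = 0.76 for an upward shift), with the kinase gene Pdk4 (ILMN_1259322) at 2.64 ± 0.14. Among the other markers at 15 h, 1 of 11 oligodendrocyte genes rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.974), 2 of 7 endothelial genes rose and 0 fell (the same adjusted over the list alone, adjusted p = 0.373) and 0 of 3 erythroid genes rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.358). Of 12 fibroblast markers 7 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.44), but the list did not pass (adjusted p = 0.0885).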

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

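The tests of both histone explanations were chosen only after the result was seen, as were the requirement that a direction hold with the block of 5 arrays and the check of the cell types one at a time. The other tests below were written before their values were seen.

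Probes of replication-dependent histone genes, a group chosen after the values were seen, read higher at every kainate time. Of 41 probes, 34, 35 and 34 rose at 5 h, 15 h and 24 h, at medians of 0.9, 1.42 and 1.35, with H2bc4 (ILMN_1242399) at 3.1 ± 0.17 and H4c8 (ILMN_2664129) at 2.44 ± 0.13 at 15 h, and H4c14 fell at 24 h (-0.35). More dividing cells could raise them, but from 5 h to 15 h the histone median moved by 0.56 and the cell cycle list by -0.32, and with the block of 5 arrays by 0.96 and 0.09, so the list lagged in both fits but fell only in the first, and this stays open. Signal shared between similar histone sequences could also raise many probes together, and although 5 of 5 histone families had a median above 0 with most of their probes called higher at 15 h, sharing within each family would give the same count, so this stays open too. The group was picked because its members rose, and how well the labelling captures histone transcripts was not tested. These arrays therefore do not settle what raised the probe signals.

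Presynaptic, cytoskeleton and calcium genes were lower at 24 h and astrocyte and neural progenitor markers higher, calls that none of these lists kept with an estimated correlation (adjusted p = 0.253, 0.244, 0.333, 0.0919 and 0.107). A lower share of neurons could give this, and would raise the markers of the other cell types alike, but their changes differed between types (permutation p = 0.0429, and 0.0185 with the detection scores as deposited). That p met the bound set beforehand, yet it rests on 3 erythroid genes, since it was 0.333 without them and 0.141 without the progenitor markers, so the share of neurons stays open. A narrower range of signals at 24 h could lower bright genes. Before normalization, the 95th percentile of the signals over their median was 20.4 to 21.6 on the 24 h arrays. On the controls it was 24.7 to 30.2. The presynaptic median stood at percentile 0 among 10000 random lists of like brightness, so the list fell beyond genes as bright. Quantile normalization had already given every array the same range, and random genes lack the correlation within a list. This test therefore cannot decide the question. Regulation within surviving neurons and loss of neurons cannot be told apart with these arrays.

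Cholesterol biosynthesis genes were lower at 15 h and 24 h, calls that were lost with an estimated correlation (adjusted p = 0.43 and 0.33). Differences between the control cultures might give this, since control replicates 1 and 3 had lower scores (10.09 and 10.12) than the other controls (10.75 to 10.77). Even so, 6 of 6 kainate arrays at these times lay below the lowest control, so the spread of these controls did not reach them. The list was taken up because it was lower in these same arrays, so this is no independent test. A culture difference of like size between the groups stays open. A narrower range of signals could also lower the list. Its median at 24 h stood at percentile 0 among random lists of like brightness, but as for the presynaptic list this test cannot decide the question. Time in culture could lower sterol synthesis too, and with 0 control arrays kept for 15 h or 24 h this stays open. Whether kainate itself lowers these genes is a hypothesis that time-matched controls would test.

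One control array stood out in a list score. Control replicate 1 had an interferon response score of 5.99 against 5.76 to 5.8 in the other controls (test statistic 0.823, past its critical value). Of the 36 groups tested, this 1 was past, where chance gives about 1 in 20.

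Between the kainate times, groups differed as follows. From 5 h to 15 h, 4672 probes changed, with list medians of 0.49 for microglia, 0.24 for neural progenitor, -0.27 for immediate early, -0.23 for presynaptic, -0.47 for cytoskeleton, -0.29 for calcium, -0.32 for cell cycle, -0.29 for ATF4 and -0.72 for cholesterol genes. With an estimated correlation none of these lists passed (adjusted p = 0.17 for immediate early, 0.462 for microglia and cytoskeleton, 0.493 for progenitor and presynaptic and 0.599 for the other genes), and with the block of 5 arrays cell cycle and ATF4 turned to 0.09 and 0.33. From 5 h to 24 h, 5038 probes changed, with medians of -0.35 for immediate early, -0.35 for presynaptic, -0.45 for cytoskeleton, -0.21 for calcium, -0.35 for cell cycle, -0.32 for ATF4 and -0.95 for cholesterol genes. None of these passed with an estimated correlation either (adjusted p = 0.0613, 0.502, 0.395, 0.674, 0.542, 0.707 and 0.542 in this order), and with the block cell cycle went to 0.02 and ATF4 turned to 0.2. From 15 h to 24 h, 86 probes changed, with medians of -0.16 for neural progenitor and -0.06 for NRF2 genes, both lost with an estimated correlation (adjusted p = 0.475 and 0.34). The number of probes changed from 15 h to 24 h ran from 7 without 15 h replicate 2 to 640 without 24 h replicate 3. It was also 56 without control replicate 4, 44, 42 and 47 without 5 h replicates 1 to 3, 12 and 9 without 15 h replicates 1 and 3, and 18 and 10 without 24 h replicates 1 and 2.

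Regrouping the arrays asks whether chance could give counts as large, with each pair of groups fitted alone. At 5 h the real grouping gave 5183 changed probes and the highest other of 84 splits 0, and 2078 against 0 by 1.5-fold. Only the real grouping, 1 of 84 splits, gave counts as large. At 15 h the counts were 6218 against 3 and 3094 against 3, and at 24 h 5138 against 69 and 2828 against 65, again 1 of 84. A split that mixes kainate and control arrays puts their difference into the spread, so few calls there are largely built in. Independent arrays are also presumed, which the labels do not state. These shares therefore describe only the regrouping of these arrays. For the number of shifted lists chance was not excluded at 5 h (20 of 84 splits as large, 10 against a highest other of 14) or at 24 h (17 of 84, 13 against 18). At 15 h 4 of 84 were as large (17 against a highest other of 21), a share just under 0.05. With the detection scores as deposited 5 of 84 were as large at 15 h, and chance was not excluded. Over all times 8665 probes changed against a highest other of 2954 in 100 regroupings, 1 as large.

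Between kainate times, 10 splits are too few for a share under 0.05. From 5 h to 15 h the real counts and the highest others were 6662 and 0 probes, 2396 and 0 by 1.5-fold, and 11 and 9 lists. From 15 h to 24 h they were 2 and 0 probes, 2 and 0 by 1.5-fold, and 4 and 3 lists. From 5 h to 24 h they were 4963 and 1 probes, 2443 and 1 by 1.5-fold, and 9 and 10 lists, where 3 splits were as large.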

How the results depend on the processing

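The block of 5 arrays, the fits without control replicates 1 and 3 and the centring on detected probes were tests chosen only after the result was seen. Over all alternatives, calls of named genes stayed the same 26203 times, were gained 528 times, lost 426 times and reversed 8 times, and calls of lists 6701, 240, 173 and 8 times.

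Background correction changed the number of probes past 1.5-fold. Probes changed by 1.5-fold or more at 5 h, probes changed by 1.5-fold or more at 15 h and probes changed by 1.5-fold or more at 24 h numbered 1205, 1889 and 1713 with no background correction and 1196, 1877 and 1698 with normexp and an offset of 50. Both compress low signals by construction.

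The count of probes changed from 15 h to 24 h, 86, was the least stable. It was 140 with no background correction, 138 with normexp, 391 after median centring, 505 in the authors' normalized table, 501 in the series matrix, 139 with no filter, 1800 with array weights, 50 with the replicate block of labelled numbers 1 to 6, 2 with only the 2 groups compared, 295 with the block of 5 arrays, 237 without control replicates 1 and 3 and 1887 without 24 h replicate 3 as well. Leaving out 1 array gave 7 to 640, with 56 without control replicate 4, 44, 42 and 47 without 5 h replicates 1 to 3, 12, 7 and 9 without 15 h replicates 1 to 3, and 18, 10 and 640 without 24 h replicates 1 to 3. The highest of these was without 24 h replicate 3, which stood apart from the other 24 h arrays. The cause was not tested. For array weights the probes changed from 5 h to 15 h numbered 7259, and the cause was not tested.

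Gene lists shifted from 15 h to 24 h, 3 in number, were 7 in the authors' normalized table, 7 in the series matrix, 5 with the stricter filter, 7 with trend and robust, 0 with array weights, 7 with the beadchip as a random block, 8 with centring on detected probes, 8 without control replicates 1 and 3 and 0 without 24 h replicate 3 as well. The counts with trend and robust and with the random block came from cameraPR. Leaving out 1 array gave 6 (control replicate 1), 5 (control replicate 4), 5 (5 h replicate 3), 1 (15 h replicate 3) and 0 (24 h replicate 3). The cause was not tested.

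A test against 1.2-fold is stricter by construction. With it, probes changed at 5 h, probes changed at 15 h and probes changed at 24 h numbered 1925, 3185 and 2898, probes changed from 5 h to 15 h 1769, probes changed from 15 h to 24 h 4 and probes changed from 5 h to 24 h 1808.

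List calls depended on the model and the test. With the beadchip as a random block, gene lists shifted at 5 h, 15 h and 24 h numbered 8, 12 and 11. With trend and robust they numbered 8, 12 and 12. With neither they numbered 11, 17 and 13, also with a fixed block for the beadchip. The random block and trend and robust were both tested with cameraPR instead of camera. Their effect on the counts therefore cannot be told apart from that of the test. From 5 h to 15 h and from 5 h to 24 h, the random block gave 11 and 10, against 10 and 8 without it. Gene lists shifted at 5 h, gene lists shifted at 15 h, gene lists shifted at 24 h, gene lists shifted from 5 h to 15 h, gene lists shifted from 15 h to 24 h and gene lists shifted from 5 h to 24 h numbered 1, 2, 1, 0, 0 and 0 with an estimated correlation between genes, 19, 27, 26, 23, 7 and 19 with fry directional, and 31, 32, 32, 32, 12 and 32 with fry mixed, which counts changes in either direction by construction. Both fry tests set a list against no change, not against the other genes, so their counts are not of the same kind as those of camera where many probes changed. Shared calls at 5 h and 24 h with separate control sets numbered 1686.

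Lists called in neither of the fits compared could also turn. With the block of 5 arrays at 5 h, the calcium list went from -0.14 to 0.2 without a call. The oxidative phosphorylation list went from 0.13 to -0.03, also without a call. Among items called in either fit, directions reversed for few. Psmd4 at 24 h was -0.18 after median centring and -0.11 in the authors' normalized table and the series matrix. Xbp1 at 24 h was -0.19, -0.13 and -0.13 there, and Zmat3 at 24 h -0.02 after median centring. The list of proteasome and ubiquitin genes from 5 h to 24 h was -0.38 in the authors' normalized table and in the series matrix. With the block of 5 arrays, Gria2 at 5 h was 0.27, the ATF4 list -0.14 and the cholesterol list 0.22 at 5 h, the cell cycle, ATF4 and oxidative phosphorylation lists 0.09, 0.33 and 0.06 from 5 h to 15 h, and the ATF4 list 0.2 from 5 h to 24 h. The cause was not tested.

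For the replicate block of labelled numbers, deviations of kainate arrays from their group means were correlated, with no block fitted. Between different times they correlated at -0.114 to 0.288 for arrays with the same number, which lay on the same beadchip. For other numbers the range was -0.277 to 0.19.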

Other observations

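No test in this part was chosen before the data were seen: the tests of the histone group, of controls 1 and 3 and of the detection scores were chosen only after the result was seen.

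Many replication-dependent histone probes, a group picked after the values were seen, were higher at 15 h. By family at 15 h, 12 of 14 H2B probes rose at a median of 2.63, 6 of 6 H3 probes at 1.9, 9 of 11 H4 probes at 1.37 and 7 of 9 H2A probes at 0.95, and the 1 H1 probe rose by 2.01. H2bc22 (ILMN_1252995), which encodes a nucleosome core protein, changed by 2.24, 2.89 and 2.75 at 5 h, 15 h and 24 h (SE 0.13). The direction of the median held under each scaling. Medians at 15 h were 1.44 after median centring and 1.53 after centring on detected probes. They were 1.15 in the authors' table and 1.6 with the block of 5 arrays. At 24 h the median of 1.35 was 0.79 in the authors' table and 0.9 with no background correction.

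Control replicates 1 and 3 stood apart from the other 4 controls in several list scores, a difference not tested for single lists. Their ATF4 scores were 9.21 and 9.23 against 8.59 to 8.64 in the others and 9.18 to 9.25 at 5 h, and their cell cycle scores 7.32 and 7.35 against 6.89 to 6.93. Lists that were lower at 15 h and 24 h were also low in these 2 controls, with calcium scores of 7.76 and 7.72 against 8.1 to 8.14 and presynaptic scores of 9.12 and 9.18 against 9.38 to 9.45.

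One target had a high signal and a detection p above 0 on exactly 5 arrays, control replicates 1 and 3 and the 5 h arrays. Background correction failed there until this target was left out of it, which was done after the data were examined. Changed probes numbered 5474 with the repair and 5539 with the scores as deposited at 5 h, 5328 of them shared in direction and 0 opposite, and the counts past 1.5-fold were 2123 and 1623. The gene annotation column of the deposited table did not match its probes, and the platform annotation was used here.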
